A study of Mus musculus with 56 samples.

How the data were processed

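Messenger RNA was measured by bulk RNA sequencing in tibialis anterior, a muscle of the lower leg, from wild-type mice and from mice heterozygous or homozygous for the titin mechanical knock-out allele. In this model the titin protein carries a recognition site for TEV, a plant virus protease, so that supplying the protease severs titin in the living muscle. Per the labels, muscles were injected with saline or with an adeno-associated virus (AAV) encoding a fusion of green fluorescent protein and TEV protease, and were dissected 3, 7 or 21 days post injection (dpi). Wild-type and homozygous muscles were sampled on all 3 days and heterozygous muscles at 7 dpi, which gave 14 groups of 3 to 5 samples and 56 samples in all. Every sample was assigned to its group by its title. No label says whether the samples of a group came from separate animals, so the p-values rest on the spread between samples, pooled over all groups, part of which may be technical.

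Per the labels' protocols, muscles were lysed with beads, total RNA was extracted with TRI reagent, and libraries were made with a directional kit (NEBNext Ultra II Directional). The submitters' processing notes name FastQC, Bowtie, RSEM, limma and the GRCm38/mm10 mouse genome, without versions. The strand setting of the counting is not given in the sources used here. RSEM divides reads that match several genes among them by estimation, so values of near-identical genes, such as immunoglobulin segments, histocompatibility genes, Hspa1a and Hspa1b, guanylate-binding proteins and neighbouring myosin heavy chains, are uncertain.

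The deposited table holds 14871 genes and 56 columns, and 0 columns were left without a sample. Its values are a signal of normalised read counts that the authors deposited on a linear scale: in every column each value equals a number of reads plus 0.5, divided by an effective library size and multiplied to a per-million scale. From these steps whole reads were recovered for 99.999% of the values, within 0.02 reads. The recovered reads per library ranged from 6.9 M to 27.18 M with a median of 21.69 M, and the second lowest library held 14.98 M. The effective library size was 0.859 to 1.493 times the read total, so the deposited column totals ranged from 669815 to 1164855. Of the gene identifiers, 14861 were found in GENCODE M21, the GRCm38 annotation used here for coordinates, and 10 were not. The table gives 19 genes an empty symbol and 16 genes a symbol turned into a date, and 23 genes share a symbol with another gene. Genes were therefore matched by identifier and named from the annotation.

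Tests were fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend, 1 mean per group and all 56 samples sharing a spread estimate per gene. A fold change on this scale understates the change of low genes. Genes with a mean of at least 1 CPM (counts per-million of the column total) were tested, which left 13017 genes and left out 1853. The viral transgene was left out of these tests and compared between groups by exact two-sided permutation tests of log2 values, with Benjamini-Hochberg adjustment over 5 comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 18 comparisons were AAV against saline within each genotype and day, differences of these responses between genotypes (interactions) and between days, and genotype differences between saline-injected muscles. Errors given with log2 changes are standard errors (SE) of the fit.

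Altogether 37 gene lists of muscle pathways and of the cell types a whole muscle can hold were written down from general knowledge. They were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists within a comparison, and again with an estimated correlation. The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names up to 10 genes with the largest rise and 10 with the largest fall in each comparison of homozygous AAV with saline muscle, and 5 and 5 in every other comparison. Such genes had to be called, to reach 5 CPM in the group where they were higher and to show no overlap between the libraries of the groups compared. Predicted genes, pseudogenes and genes without a symbol were passed over. The rule always names Ttn, Ankrd1, Ankrd2, Csrp3, Myh3, Trim63, Fbxo32, Cdkn1a, Cd8a, Adgre1, Col1a1, Isg15 and Ppargc1a, and up to 4 members with the smallest p of each list described. Where space did not allow all of them, fewer are named.

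The planned test assumed normalised values or counts in the file. Because the values are normalised, limma on the log scale stayed the main test, and edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma voom on the recovered reads were run as alternatives. Other alternatives were pseudocounts of 0.25 and 4, no filter or a higher one, median-of-ratios rescaling, quantile normalization, a fit of only the groups compared, array weights, robust variance estimation, the replicate number as a block, direct comparison of AAV-injected muscles between genotypes, fry in place of camera, and leaving out each library in turn. The voom fit and the direct comparison of homozygous with heterozygous AAV muscle were added after seeing the data.

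Replicate numbers in the labels pair the samples in 2 of 7 sets of AAV and saline muscles. In heterozygous muscle at 7 dpi the deviations of same-numbered libraries from their group means correlated at 0.13 to 0.18, and in homozygous muscle at 21 dpi at 0.16 to 0.23, above the limit of 0.1 in all 4 pairs of each set. Nothing in the labels says what a shared number marks. No pair of replicates agreed within sampling noise, since the smallest chi-square per degree of freedom was 7.7, and all libraries were kept as separate samples.

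The limma fit was tested on simulated counts of 13017 genes, 200 of them changed by known folds. In comparisons of 2 groups it recovered 28.4% to 58.2% of 1.5-fold, 68.7% to 83.6% of 2-fold and 87.9% to 97% of 4-fold changes, and in differences between responses 13.4% to 25.4%, 52.2% to 68.7% and 81.8% to 90.9%. For wild-type AAV against saline, 1.5-fold and 2-fold recovery was 28.4% and 83.6% at 3 dpi and 50.7% and 73.1% at 7 dpi. False calls were 11 of 149 and 14 of 155 there, and 1 to 11 in other comparisons. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.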

Results

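Transcript levels were measured in 56 tibialis anterior muscles by bulk RNA sequencing, in 14 groups set by genotype, injection and day. Saline-injected and AAV-injected muscles numbered 3 and 5, 3 and 4, and 4 and 4 at 3, 7 and 21 dpi in wild-type mice. They numbered 4 and 4, 4 and 5, and 4 and 4 in homozygous mice, and 4 and 4 at 7 dpi in heterozygous mice. The viral TEV protease cleaves titin, the giant spring protein of the sarcomere, where the mechanical knock-out allele supplies the site. The study asked what titin cleavage does to muscle. Wild-type muscle given the same virus measured the response to vector and protease alone. Transgene levels differed between genotypes at 7 dpi, and 4-fold at 3 dpi without passing, so responses were not compared at equal levels. Only homozygous AAV replicate 2 at 7 dpi, with 6.9 M reads, lay under 14.98 M. Values are normalised read counts as deposited, and changes are log2 ± SE from limma with adjusted p-values. Along the first principal component, which held 50.6% of the variance, saline groups had means of 14.2 to 33.2. The AAV groups lay at 17.4 ± 11.5 (SD, n = 5) and 27.7 ± 5.5 (n = 4) in wild-type muscle at 3 and 7 dpi, and at -34 ± 24.1 (n = 4) at 21 dpi. Homozygous AAV groups lay at -30.4 ± 15.9 (n = 4), -37.7 ± 9.2 (n = 5) and -72 ± 28.2 (n = 4) on the same days, and heterozygous AAV muscle at -21 ± 9 (n = 4).

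Viral transgene messenger RNA was present in all AAV libraries, at 56 to 34407 reads, and saline libraries held 0 to 6 reads. The targeted titin gene itself (Ttn, minus strand of chromosome 2) checks nothing about the labels, because the protein and not the transcript is cleaved. In wild-type muscle the transgene stood at 17.2 ± 18.1 normalised counts at 3 dpi (SD, n = 5), 240 ± 68.3 at 7 dpi (n = 4) and 756 ± 499 at 21 dpi (n = 4). In homozygous muscle it stood at 49.4 ± 21.8 (n = 4), 22.4 ± 5.39 (n = 5) and 640 ± 431 (n = 4). Heterozygous muscle held 86.6 ± 24.1 at 7 dpi (n = 4). At 7 dpi the homozygous level was 10.6-fold below the wild-type level (log2 difference -3.41, exact permutation p = 0.0079, adjusted p = 0.02, n = 5 and 4) and 3.84-fold below the heterozygous level (log2 difference -1.94, exact permutation p = 0.0079, adjusted p = 0.02). The heterozygous level was 2.76-fold below the wild-type level (log2 difference -1.47, exact permutation p = 0.029, adjusted p = 0.048, n = 4 and 4), and 0.029 is the smallest p that this design allows. At 3 dpi the homozygous level was 4-fold above the wild-type level, but did not pass after adjustment (exact permutation p = 0.048, adjusted p = 0.06, n = 4 and 5). At 21 dpi the log2 difference was -0.17 (exact permutation p = 0.8, adjusted p = 0.8, n = 4 and 4), with a spread between libraries from 111 to 1270 in wild-type muscle. Without heterozygous AAV replicate 2 the difference between heterozygous and wild-type muscle was -1.28 (exact permutation p = 0.057, not adjusted, n = 3 and 4).

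**Figure D1:**
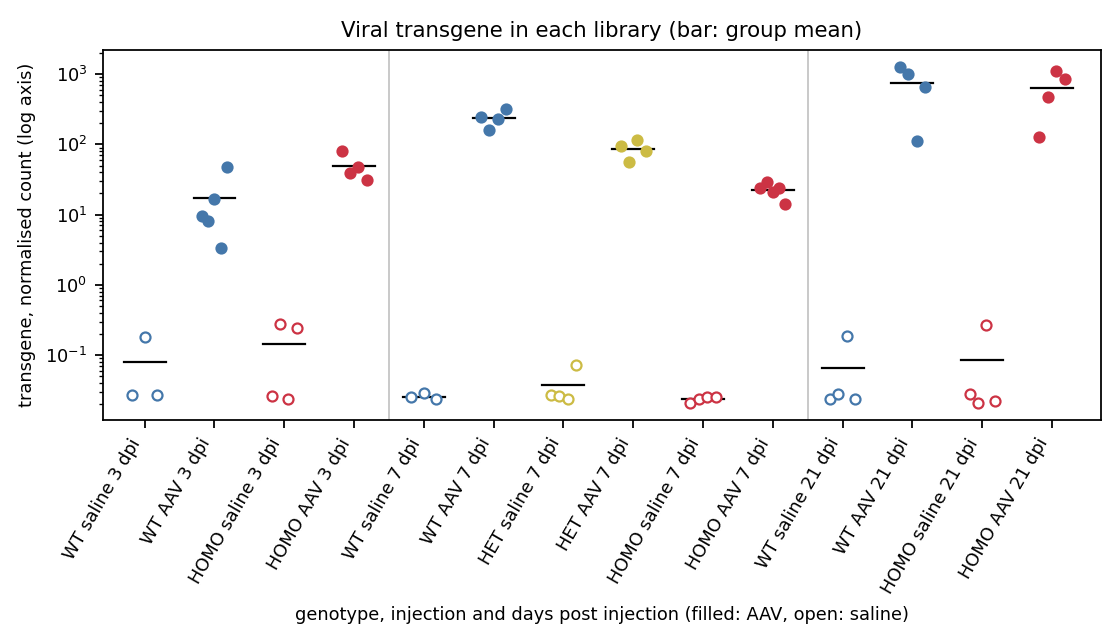
Normalised read count of the viral transgene (vertical axis, log scale) in each library (points) of the 14 groups, with group means as bars. All saline libraries lie at 0 to 6 reads, and at 7 dpi the 5 homozygous AAV libraries (14.3 to 29) lie below the 4 wild-type AAV libraries (158 to 324).

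At 3 dpi in homozygous muscle most measured genes of the macrophage, matrix, unfolded protein response and ribosome biogenesis lists rose and most of mitochondrial energy supply fell, but with an estimated correlation only the calls of the unfolded protein response and ribosome biogenesis lists held. The largest rises were those of Mt2, a metal-binding metallothionein (chromosome 8, 94172664 to 94173568 of GRCm38, 4.81 ± 0.44, adjusted p = 4.85e-11), and Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050, 4.61 ± 0.48, adjusted p = 9.19e-10). Rrad, a small Ras-related GTPase, rose by 4.00 ± 0.48, the protease inhibitor gene Timp1 by 3.99 ± 0.37, the matrix glycoprotein gene Tnc by 3.75 ± 0.48, and Lgals3, Gpnmb and Ctss, which are abundant in activated macrophages, by 3.86 ± 0.47, 3.69 ± 0.43 and 3.54 ± 0.46. Ankrd1, which encodes a stress-induced ankyrin repeat protein that binds titin (chromosome 19, 36111961 to 36120099), rose by 3.44 ± 0.61, adjusted p = 2.46e-05. Among the largest falls were Myl2, the slow and cardiac regulatory myosin light chain (-2.21 ± 0.65), Nos1, the neuronal nitric oxide synthase of the sarcolemma (-1.40 ± 0.21), the water channel gene Aqp4 (-1.39 ± 0.26) and Kdr, a receptor for vascular endothelial growth factor (-1.32 ± 0.19). In total 4505 of 13017 genes were called, 2260 higher and 2245 lower, and 654 of them changed by 2-fold or more.

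Of 20 macrophage markers measured at 3 dpi, 19 rose, 0 fell and 1 did not pass (19 rose adjusted over the list alone, camera adjusted p = 5.48e-19, adjusted p = 0.107 with an estimated correlation). Ccl2, a monocyte-attracting chemokine, stood at 3.28 ± 0.27 and Adgre1, which encodes F4/80, at 2.34 ± 0.36. Of 24 matrix and fibrosis genes 19 rose, 0 fell and 5 did not pass (19 rose and 1 fell adjusted over the list alone, camera adjusted p = 6.08e-09, adjusted p = 0.317 with an estimated correlation), among them the collagen gene Col1a1 (1.33 ± 0.34). Of 19 genes of the integrated stress and unfolded protein responses 15 rose, 0 fell and 4 did not pass (15 rose adjusted over the list alone, camera adjusted p = 6.45e-10, adjusted p = 0.000681 with an estimated correlation). Its leading members were Psat1, an enzyme of serine synthesis (2.82 ± 0.32), Sdf2l1 (1.87 ± 0.20), Hyou1 (0.92 ± 0.10) and Calr (0.78 ± 0.08), which act in folding within the endoplasmic reticulum. Of 18 ribosome biogenesis genes 12 rose, 0 fell and 6 did not pass (13 rose adjusted over the list alone, camera adjusted p = 1.19e-05, adjusted p = 0.0473 with an estimated correlation). The transcription factor gene Myc stood at 1.77 ± 0.24 and the nucleolar protein gene Nop58 at 0.75 ± 0.12. Of 22 heat shock and chaperone genes 11 rose, 1 fell and 10 did not pass (12 rose and 2 fell adjusted over the list alone, camera adjusted p = 6.85e-05, adjusted p = 0.317 with an estimated correlation), led by Hspb8 (1.20 ± 0.16) and by Hspa1b (2.85 ± 0.41), whose reads are hard to part from those of Hspa1a. Of 16 proliferation genes 14 rose, 0 fell and 2 did not pass (16 rose adjusted over the list alone, camera adjusted p = 6.45e-10, adjusted p = 0.194 with an estimated correlation). Top2a stood at 2.47 ± 0.37 and Mki67 at 2.42 ± 0.37. Trim63, a ubiquitin ligase of muscle atrophy, rose by 0.93 ± 0.17, and Cdkn1a, a cell cycle inhibitor, by 1.04 ± 0.29.

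In the same libraries, in which macrophage markers rose by a median of 2.56, all members of the nuclear-encoded oxidative phosphorylation list but 1 fell. Of its 25 genes 0 rose, 24 fell and 1 did not pass (25 fell adjusted over the list alone, camera adjusted p = 5.64e-15, adjusted p = 0.236 with an estimated correlation). Cycs (cytochrome c) stood at -0.70 ± 0.10 and Uqcrc2 (complex III) at -0.61 ± 0.09. Of 20 fatty acid oxidation genes 0 rose, 17 fell and 3 did not pass (19 fell adjusted over the list alone, camera adjusted p = 2.52e-07, adjusted p = 0.317 with an estimated correlation), including Ppargc1a, a coactivator of mitochondrial biogenesis (-0.87 ± 0.18), and Cpt1b, which admits fatty acids to mitochondria (-0.79 ± 0.16). Of 20 glycolysis and glycogen genes 0 rose, 16 fell and 4 did not pass (16 fell adjusted over the list alone, camera adjusted p = 6.31e-08, adjusted p = 0.317 with an estimated correlation). Tpi1 stood at -0.62 ± 0.12 and Pgam2 at -0.74 ± 0.15, and 10 of the list fell under quantile normalization. Of 14 fast fibre genes 0 rose, 13 fell and 1 did not pass (14 fell adjusted over the list alone, camera adjusted p = 3.39e-05, adjusted p = 0.412 with an estimated correlation), with 2 falls under quantile normalization. Of 13 genes encoded by mitochondrial DNA 0 rose, 13 fell and 0 did not pass (13 fell adjusted over the list alone, camera adjusted p = 6.22e-05, adjusted p = 0.412 with an estimated correlation), with 1 fall under quantile normalization. Ttn fell by 0.55 on the log2 scale as deposited (adjusted p = 0.000798), stood at 0 under quantile normalization and did not pass when only these groups were fitted (adjusted p = 0.0561). The fast fibre gene Myh2 was called at -1.37 ± 0.43, a call that ended under quantile normalization and without homozygous AAV replicate 3.

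At 7 dpi developmental myosin and matrix genes were among the largest rises in homozygous muscle, and no call of a list held with an estimated correlation. Myh8, the perinatal myosin heavy chain (chromosome 11, 67277124 to 67308634), rose by 4.55 ± 0.50, adjusted p = 2.35e-09, Myh3, the embryonic heavy chain (chromosome 11, 67078300 to 67102291), by 3.39 ± 0.55, adjusted p = 3.87e-06, and the embryonic light chain gene Myl4 by 3.65 ± 0.44. Sln, which encodes sarcolipin, an inhibitor of the sarcoplasmic calcium pump, rose by 4.34 ± 0.43, and Ankrd1 by 3.84 ± 0.58, from a mean of 47.2 ± 36.5 (SD, n = 4) to 589 ± 291 normalised counts (n = 5). The matrix genes Postn (periostin) and Mmp13, a collagenase (chromosome 9, 7272514 to 7283331), rose by 4.18 ± 0.35 and 3.84 ± 0.43, the protease inhibitor genes Serpina3n and Serpinb1a by 3.51 ± 0.24 and 3.67 ± 0.36, and Mt2 by 3.71 ± 0.42. Largest among the falls were Myl3, the slow and cardiac essential light chain (-3.66 ± 0.51), Ces1d, a carboxylesterase of lipid metabolism (-2.70 ± 0.36), Nmrk2, a nicotinamide riboside kinase of muscle (-2.41 ± 0.29), Myl2 (-2.27 ± 0.62), Nos1 (-2.04 ± 0.20) and the lipid droplet gene Plin4 (-1.85 ± 0.32). In total 5616 genes were called, 2687 higher and 2929 lower, 761 of them by 2-fold or more.

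Of 24 matrix genes at 7 dpi 22 rose, 0 fell and 2 did not pass (22 rose adjusted over the list alone, camera adjusted p = 1.46e-14, adjusted p = 0.29 with an estimated correlation). Lox, which crosslinks collagen, stood at 3.01 ± 0.31, Bgn at 2.18 ± 0.23, Col3a1 at 2.12 ± 0.24 and Col1a1 at 2.40 ± 0.32. Of 20 macrophage markers 19 rose, 0 fell and 1 did not pass (19 rose adjusted over the list alone, camera adjusted p = 5.17e-12, adjusted p = 0.29 with an estimated correlation). The complement gene C1qb stood at 2.52 ± 0.37, Cd14 at 1.52 ± 0.20 and Adgre1 at 2.22 ± 0.34. Of 8 developmental contractile genes 5 rose, 0 fell and 3 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.000534, adjusted p = 0.348 with an estimated correlation). Of 24 interferon response genes 15 rose, 0 fell and 9 did not pass (18 rose adjusted over the list alone, camera adjusted p = 8.48e-06, adjusted p = 0.46 with an estimated correlation). Mx1 stood at 1.87 ± 0.31, Zbp1 at 1.82 ± 0.36 and Isg15 at 1.27 ± 0.35. Of 16 antigen presentation genes 11 rose, 0 fell and 5 did not pass (14 rose adjusted over the list alone, camera adjusted p = 2.9e-05, adjusted p = 0.46 with an estimated correlation). The class II genes H2-Eb1 and H2-Aa stood at 2.13 ± 0.32 and 2.13 ± 0.34. Cdkn1a rose by 1.45 ± 0.27. The T cell coreceptor gene Cd8a was called at 0.87 ± 0.32, and this call ended under 4 alternatives, with a largest adjusted p of 0.259.

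Most energy supply and vessel genes fell at 7 dpi in the libraries in which macrophage markers rose by a median of 2.03. Of 25 oxidative phosphorylation genes 0 rose, 25 fell and 0 did not pass (25 fell adjusted over the list alone, camera adjusted p = 1.56e-15, adjusted p = 0.29 with an estimated correlation). Atp5b (ATP synthase) stood at -0.77 ± 0.09 and Sdha (complex II) at -0.81 ± 0.10. Of 13 mitochondrially encoded genes 0 rose, 13 fell and 0 did not pass (13 fell adjusted over the list alone, camera adjusted p = 2.19e-08, adjusted p = 0.348 with an estimated correlation), led by mt-Nd5 (-1.04 ± 0.17) and mt-Co1 (-1.06 ± 0.17), and 6 fell under quantile normalization, which ended the mt-Co1 call. Of 20 fatty acid oxidation genes 0 rose, 16 fell and 4 did not pass (16 fell adjusted over the list alone, camera adjusted p = 2.96e-06, adjusted p = 0.442 with an estimated correlation). Ppargc1a stood at -0.85 ± 0.18. Of 20 glycolysis genes 0 rose, 12 fell and 8 did not pass (13 fell adjusted over the list alone, camera adjusted p = 7.98e-05, adjusted p = 0.46 with an estimated correlation). Hk2 (hexokinase 2) stood at -0.92 ± 0.14, while 6 of the list fell and 2 rose under quantile normalization. Of 12 endothelial genes 0 rose, 9 fell and 3 did not pass (10 fell adjusted over the list alone, camera adjusted p = 9.59e-05, adjusted p = 0.376 with an estimated correlation). Kdr stood at -1.27 ± 0.18 and the receptor gene Tie1 at -0.84 ± 0.14. Of 14 fast fibre genes 0 rose, 10 fell and 4 did not pass (11 fell adjusted over the list alone, camera adjusted p = 0.00085, adjusted p = 0.46 with an estimated correlation), and their median changed from -0.47 as deposited to 0.03 under quantile normalization. Ttn fell by 0.57 on the log2 scale as deposited (adjusted p = 0.000215) and stood at 0.21 under quantile normalization.

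At 21 dpi homozygous muscle showed its widest change, with embryonic myosin and genes of interferon, lymphocytes and antigen presentation among the largest rises. Myh3 rose by 5.60 ± 0.59, adjusted p = 4.73e-11, from 9.57 ± 4.25 (SD, n = 4) to 570 ± 279 normalised counts (n = 4). The interferon-induced chemokine genes Cxcl9 (chromosome 5, 92321347 to 92328079) and Cxcl10 rose by 5.59 ± 0.47, adjusted p = 1.52e-13, and 4.88 ± 0.37, and the interferon-inducible GTPase genes Iigp1, Gbp10 and Gbp6 by 5.29 ± 0.63, 4.93 ± 0.52 and 4.75 ± 0.55. Igkc, the constant segment of the immunoglobulin kappa chain (chromosome 6, 70726435 to 70726966), rose by 5.11 ± 0.42, the macrophage genes Ctss and Mpeg1 by 5.07 ± 0.46 and 4.89 ± 0.44, Sln by 4.72 ± 0.45 and Ankrd1 by 4.10 ± 0.61. Largest among the falls were Ces1d (-3.12 ± 0.38), Fam57b (-2.88 ± 0.29), Myl3 (-2.71 ± 0.53), Plin4 (-2.70 ± 0.34), Nos1 (-2.52 ± 0.21) and Adhfe1, a mitochondrial dehydrogenase (-2.38 ± 0.21). In total 7714 genes were called, 3863 higher and 3851 lower, and 1994 of them changed by 2-fold or more. Quantile normalization moved the median change of all genes from 0 to -0.116.

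Immune lists rose nearly whole at 21 dpi. Of 13 T and natural killer cell markers 13 rose, 0 fell and 0 did not pass (13 rose adjusted over the list alone, camera adjusted p = 1.63e-13, adjusted p = 0.24 with an estimated correlation). The T cell kinase gene Lck stood at 3.53 ± 0.26, Ccl5 at 4.72 ± 0.35 and Cd8a at 3.95 ± 0.34. Of 16 antigen presentation genes 16 rose, 0 fell and 0 did not pass (16 rose adjusted over the list alone, camera adjusted p = 7.51e-14, adjusted p = 0.24 with an estimated correlation). H2-Eb1 stood at 4.69 ± 0.34 and the immunoproteasome gene Psmb10 at 2.79 ± 0.22. Of 24 interferon response genes 24 rose, 0 fell and 0 did not pass (24 rose adjusted over the list alone, camera adjusted p = 7.68e-11, adjusted p = 0.24 with an estimated correlation). Isg15 stood at 1.86 ± 0.37. Of 20 macrophage markers 19 rose, 0 fell and 1 did not pass (19 rose adjusted over the list alone, camera adjusted p = 1.9e-10, adjusted p = 0.24 with an estimated correlation). C1qa stood at 4.19 ± 0.37 and Adgre1 at 3.75 ± 0.36. Of 4 measured B and plasma cell markers 4 rose, 0 fell and 0 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.24 with an estimated correlation). Jchain, which joins secreted antibodies, stood at 3.62 ± 0.36. Of 24 matrix genes 22 rose, 0 fell and 2 did not pass (22 rose adjusted over the list alone, camera adjusted p = 1.32e-06, adjusted p = 0.319 with an estimated correlation). Col1a1 stood at 1.80 ± 0.34. Of 16 proliferation genes 15 rose, 0 fell and 1 did not pass (15 rose adjusted over the list alone, camera adjusted p = 5.46e-07, adjusted p = 0.24 with an estimated correlation). Mki67 stood at 3.38 ± 0.37. Cdkn1a rose by 1.90 ± 0.29.

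Most energy supply and vessel genes fell at 21 dpi in the libraries in which T cell markers rose by a median of 3.35. Of 25 oxidative phosphorylation genes 0 rose, 25 fell and 0 did not pass (25 fell adjusted over the list alone, camera adjusted p = 3.17e-18, adjusted p = 0.24 with an estimated correlation). Cycs stood at -1.26 ± 0.10 and Ndufs1 (complex I) at -1.26 ± 0.10. Of 13 mitochondrially encoded genes 0 rose, 13 fell and 0 did not pass (13 fell adjusted over the list alone, camera adjusted p = 9.17e-10, adjusted p = 0.24 with an estimated correlation). Among these mt-Nd1 stood at -1.49 ± 0.16, and at -0.39 under quantile normalization, where 10 of the list fell. Of 20 fatty acid oxidation genes 0 rose, 19 fell and 1 did not pass (19 fell adjusted over the list alone, camera adjusted p = 1.53e-08, adjusted p = 0.24 with an estimated correlation). Acadm, a dehydrogenase of medium-chain fatty acids, stood at -1.43 ± 0.16 and Ppargc1a at -1.19 ± 0.18. Of 20 glycolysis genes 0 rose, 19 fell and 1 did not pass (19 fell adjusted over the list alone, camera adjusted p = 2.05e-07, adjusted p = 0.279 with an estimated correlation). Hk2 stood at -1.25 ± 0.14, while 12 of the list fell and 2 rose under quantile normalization. Of 12 endothelial genes 0 rose, 11 fell and 1 did not pass (11 fell adjusted over the list alone, camera adjusted p = 1.69e-05, adjusted p = 0.24 with an estimated correlation). Kdr stood at -1.65 ± 0.19. Of 14 fast fibre genes 0 rose, 12 fell and 2 did not pass (12 fell adjusted over the list alone, camera adjusted p = 0.000156, adjusted p = 0.357 with an estimated correlation). Myh4, the fastest heavy chain, stood at -1.85 ± 0.23, and at -0.54 under quantile normalization, where 4 of the list fell and 3 rose. Of 26 sarcomere genes 2 rose, 15 fell and 9 did not pass (2 rose and 15 fell adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.475 with an estimated correlation), and their median changed from -0.39 as deposited to 0.12 under quantile normalization. Ttn, at -0.87 ± 0.13 as deposited, was called higher under quantile normalization (0.43, adjusted p = 0.000352). The ubiquitin ligase gene Fbxo32 stood at -1.12 ± 0.28, and Trim63 was called at -0.41 ± 0.17, a call that ended under 8 alternatives (largest adjusted p = 0.529).

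**Figure D2:**
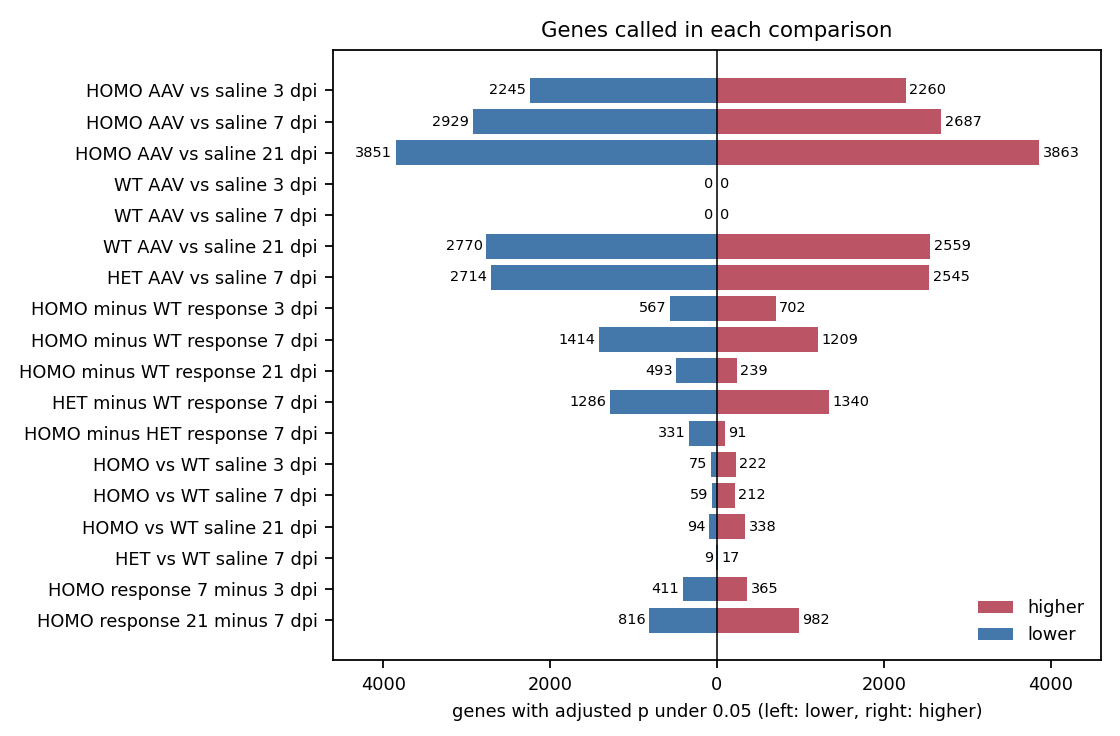
Number of genes called higher or lower (horizontal axis, limma adjusted p under 0.05, of 13017 tested) in each of the 18 comparisons. Wild-type AAV against saline muscle shows 0 calls at 3 and 7 dpi and 5329 at 21 dpi.

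Wild-type muscle given the same virus showed 0 called genes at 3 dpi and 0 at 7 dpi by limma. At an unadjusted p under 0.05 the fit gave 430 genes at 3 dpi and 210 at 7 dpi. With the recovered reads, edgeR called 0 and 0, DESeq2 8 and 7, and limma voom 0 and 0. Of 20 macrophage markers at 3 dpi 0 rose, 0 fell and 20 did not pass (1 rose adjusted over the list alone, camera adjusted p = 2.57e-15, adjusted p = 0.65 with an estimated correlation), with a median of 0.74, and Adgre1 stood at 1.23 ± 0.37, adjusted p = 1. Wild-type AAV replicate 3 stood apart from the other 4 libraries of its group in this marker, at 10.6 normalised counts against 4.46 to 5.69, and in its place on the first principal component, at -1.7 against 14.9 to 26.6. No list was called at 7 dpi.

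At 21 dpi wild-type muscle showed a response of its own, with immunoglobulins, embryonic myosin and interferon-linked genes among the largest rises. Igkc rose by 6.76 ± 0.42, adjusted p = 6.07e-17, and Ighg2b and Ighg2c, heavy chain segments whose reads are shared, by 5.39 ± 0.34 and 6.43 ± 0.58. Jchain rose by 5.32 ± 0.36, Myh3 by 5.33 ± 0.59, adjusted p = 1.36e-09, Myh8 by 5.02 ± 0.53, and Ankrd1 by 3.43 ± 0.61. The falls were smaller, with Adhfe1 at -1.47 ± 0.21, Fgfbp1 at -1.46 ± 0.27 and Nt5c1a, a nucleotidase of muscle, at -1.39 ± 0.22. Of 13 T and natural killer cell markers 13 rose, 0 fell and 0 did not pass (13 rose adjusted over the list alone, camera adjusted p = 3.87e-15, adjusted p = 0.121 with an estimated correlation). Lck stood at 2.61 ± 0.26 and Cd8a at 2.25 ± 0.34. Of 4 B and plasma cell markers 4 rose, 0 fell and 0 did not pass (4 rose adjusted over the list alone, camera adjusted p = 4.57e-06, adjusted p = 0.0877 with an estimated correlation). Of 16 antigen presentation genes 16 rose, 0 fell and 0 did not pass (16 rose adjusted over the list alone, camera adjusted p = 3.33e-19, adjusted p = 0.102 with an estimated correlation). H2-K1 stood at 3.01 ± 0.29. Of 24 interferon response genes 24 rose, 0 fell and 0 did not pass (24 rose adjusted over the list alone, camera adjusted p = 2.07e-15, adjusted p = 0.185 with an estimated correlation). Isg15 stood at 1.96 ± 0.37. Of 20 macrophage markers 18 rose, 0 fell and 2 did not pass (18 rose adjusted over the list alone, camera adjusted p = 3.32e-14, adjusted p = 0.185 with an estimated correlation). Adgre1 stood at 3.06 ± 0.36. Of 24 matrix genes 21 rose, 0 fell and 3 did not pass (22 rose adjusted over the list alone, camera adjusted p = 1.65e-11, adjusted p = 0.196 with an estimated correlation). Col1a1 stood at 1.94 ± 0.34. Of 8 developmental contractile genes 6 rose, 0 fell and 2 did not pass (6 rose adjusted over the list alone, camera adjusted p = 2.11e-05, adjusted p = 0.185 with an estimated correlation).

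At 21 dpi fewer oxidative phosphorylation and glycolysis genes were called in wild-type muscle, beside a median rise of 2.19 in T cell markers. In the oxidative phosphorylation list (25 measured) 0 rose, 14 fell and 11 did not pass (16 fell adjusted over the list alone, camera adjusted p = 5.83e-05, adjusted p = 0.473 with an estimated correlation). Cox6a2 stood at -0.71 ± 0.13, and 1 fell under quantile normalization. Of 20 glycolysis genes 0 rose, 8 fell and 12 did not pass (9 fell adjusted over the list alone, camera adjusted p = 0.00934, adjusted p = 0.533 with an estimated correlation), with a median of -0.26 as deposited and 0 under quantile normalization. Cdkn1a rose by 1.68 ± 0.29. Ttn stood at -0.53 ± 0.13 as deposited, and this call ended under quantile normalization (-0.06). In total 5329 genes were called, 2559 higher and 2770 lower, 1058 of them by 2-fold or more. Among these genes 2255 were also higher and 2286 also lower in homozygous muscle at 21 dpi, against 759.4 and 819.5 for independent lists, and the changes correlated across genes at 0.897, though genes are not independent replicates. Calls of Arrdc2 (-2.31 ± 0.74) and Slc25a25 (-1.45 ± 0.56) ended without single libraries, under 1 and 5 such fits, and that of Slc25a25 also under quantile normalization, with largest adjusted p of 0.068 and 0.127.

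Tests of homozygous minus wild-type responses called 1269 genes at 3 dpi (reached by 5 of 100 regroupings), 702 of them higher. Homozygous muscle held 4-fold more transgene (exact permutation adjusted p = 0.06). Spp1 (4.04 ± 0.69), Mt2 (4.00 ± 0.64, adjusted p = 7.72e-05), Timp1 (3.64 ± 0.54), Rrad (3.44 ± 0.69) and Tnc (3.37 ± 0.69) led, and Trim63 differed by 1.03 ± 0.24. The responses of Scara5, a ferritin receptor (-1.50 ± 0.31), and Kdr (-1.36 ± 0.27) were lower. Of 19 stress and unfolded protein response genes 11 were higher, 0 were lower and 8 did not pass (13 higher adjusted over the list alone, camera adjusted p = 4.08e-10, adjusted p = 0.00057 with an estimated correlation). Of 18 ribosome biogenesis genes 5 were higher, 0 were lower and 13 did not pass (11 higher adjusted over the list alone, camera adjusted p = 1.96e-06, adjusted p = 0.0226 with an estimated correlation). Of 25 oxidative phosphorylation genes 0 were higher, 21 were lower and 4 did not pass (23 lower adjusted over the list alone, camera adjusted p = 5.37e-16, adjusted p = 0.24 with an estimated correlation), and 9 were lower under quantile normalization. Differences in Ankrd1 (2.93 ± 0.88) and Ppargc1a (-0.81 ± 0.27) were called but lost under 10 and 14 alternatives, and those in Spp1, Timp1 and Rrad with voom (largest adjusted p = 0.157, 0.0728 and 0.0858). The count was 625 and 2314 without homozygous AAV replicates 3 and 4 and 836 without wild-type saline replicate 3.

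At 7 dpi the same test called 2623 genes, 1209 with a higher and 1414 a lower response in homozygous muscle (10.6-fold less transgene). Mmp13 (5.22 ± 0.65, adjusted p = 4.54e-07), Myh8 (4.84 ± 0.76), Postn (4.63 ± 0.54), Sln (4.39 ± 0.65) and Ankrd1 (4.28 ± 0.88) responded more strongly, as did Col1a1 (2.60 ± 0.48), Myh3 (3.21 ± 0.84) and Adgre1 (2.32 ± 0.51). Myl3 (-3.63 ± 0.77), Ces1d (-2.82 ± 0.55) and Ppargc1a (-0.97 ± 0.27) had the lower response. Of 24 matrix genes 18 were higher, 0 were lower and 6 did not pass (18 higher adjusted over the list alone, camera adjusted p = 1.33e-14, adjusted p = 0.333 with an estimated correlation). Of 22 autophagy and lysosome genes 6 were higher, 0 were lower and 16 did not pass (7 higher adjusted over the list alone, camera adjusted p = 0.000486, adjusted p = 0.0487 with an estimated correlation), and 10 were higher under quantile normalization. Among oxidative phosphorylation genes (25 measured) 0 were higher, 19 were lower and 6 did not pass (23 lower adjusted over the list alone, camera adjusted p = 1.7e-14, adjusted p = 0.333 with an estimated correlation). Of 14 fast fibre genes 0 were higher, 3 were lower and 11 did not pass (3 lower adjusted over the list alone, camera adjusted p = 0.0191, adjusted p = 0.649 with an estimated correlation), with a median of -0.4 as deposited and 0.06 under quantile normalization. The difference in Myl2 (-2.74 ± 0.94) ended under 12 alternatives and stood at 0.15 between the AAV-injected muscles themselves, that in Ttn (-0.52 ± 0.19) ended under 14 and stood at 0.15 under quantile normalization, and voom ended those of Sln, Myh3 and Adgre1 (largest adjusted p = 0.102, 0.187 and 0.0988).

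At 21 dpi 732 genes differed in response, 239 with a higher and 493 with a lower response in homozygous muscle. Of 25 oxidative phosphorylation genes 0 were higher, 23 were lower and 2 did not pass (24 lower adjusted over the list alone, camera adjusted p = 4.57e-37, adjusted p = 0.0596 with an estimated correlation). Cycs stood at -1.03 ± 0.14, adjusted p = 6.87e-06 and Uqcrfs1 at -0.96 ± 0.15. Of 13 mitochondrially encoded genes 0 were higher, 10 were lower and 3 did not pass (13 lower adjusted over the list alone, camera adjusted p = 5.68e-11, adjusted p = 0.356 with an estimated correlation), and 2 were lower under quantile normalization. Of 13 T and natural killer cell markers 5 were higher, 0 were lower and 8 did not pass (11 higher adjusted over the list alone, camera adjusted p = 7.93e-08, adjusted p = 0.402 with an estimated correlation). The chemokine gene Cx3cl1 (2.49 ± 0.52), the desmosome gene Dsp (2.95 ± 0.41) and Ripply1 (2.77 ± 0.32) responded more strongly, but the calls of Dsp and Ripply1 ended with edgeR, DESeq2 and voom and that of Cx3cl1 with voom (largest adjusted p = 0.472, 0.916 and 0.121). Differences in Sln (2.16 ± 0.64), Cd8a (1.70 ± 0.48), Ces1d (-1.82 ± 0.54) and Jchain (3.25-fold lower) ended under 14, 9, 13 and 13 alternatives. The count was 121 when only the groups compared were fitted and 2269 with array weights. It was 454 without wild-type AAV replicate 1, 404 without replicate 2, 438 without homozygous AAV replicate 2, 416 without replicate 3 and 1992 without replicate 4.

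In heterozygous muscle at 7 dpi most measured genes of the titin-linked mechanosensing, chaperone and matrix lists rose, but no call of a list held with an estimated correlation. Ankrd1 rose by 6.07 ± 0.61, adjusted p = 1.13e-10, from 5.85 ± 1.95 (SD, n = 4) to 461 ± 131 normalised counts (n = 4). Csrp3, which encodes the muscle LIM protein of the Z-disc (chromosome 7, 48830398 to 48848033), rose by 3.97 ± 0.68, adjusted p = 8.78e-06, from 90.6 ± 77.8 to 1136 ± 255, and Ankrd2 by 2.76 ± 0.56. Cilp, a cartilage matrix protein gene (chromosome 9, 65265180 to 65280605), rose by 5.10 ± 0.40, Postn by 4.61 ± 0.37, Myh3 by 4.46 ± 0.59, and the keratin gene Krt18 by 4.37 ± 0.45. Ces1d (-2.30 ± 0.38), Klhl33 (-2.02 ± 0.32), Fam57b (-1.88 ± 0.29) and Magix (-1.88 ± 0.21) fell. In total 5259 genes were called, 2545 higher and 2714 lower, 787 of them by 2-fold or more. Of the 2687 genes higher in homozygous muscle on that day, 1618 were also higher in heterozygous muscle (525.3 for independent lists), and 1910 were lower in both (610.7 for independent lists). Opposite calls in heterozygous muscle were found for 7 of the genes higher and 40 of those lower in homozygous muscle, and changes correlated across genes at 0.76.

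Of 24 titin-linked mechanosensing genes in heterozygous muscle 14 rose, 3 fell and 7 did not pass (14 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.356 with an estimated correlation). Xirp2 stood at 1.78 ± 0.15, Smpx at 1.00 ± 0.12 and the chaperone gene Cryab at 2.04 ± 0.29. The 3 that fell were Trim55, Ankrd23 and Capn3, and Trim63 rose by 0.68 ± 0.17. Of 22 heat shock and chaperone genes 13 rose, 1 fell and 8 did not pass (13 rose and 1 fell adjusted over the list alone, camera adjusted p = 8.83e-06, adjusted p = 0.291 with an estimated correlation). Hspb1 stood at 3.06 ± 0.25 and Hspb8 at 2.18 ± 0.16. Of 24 matrix genes 23 rose, 0 fell and 1 did not pass (23 rose adjusted over the list alone, camera adjusted p = 2.52e-16, adjusted p = 0.281 with an estimated correlation). Col1a1 stood at 2.46 ± 0.34. Of 8 developmental contractile genes 6 rose, 0 fell and 2 did not pass (6 rose adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.291 with an estimated correlation). Myh8 stood at 4.05 ± 0.53 and Myl6b at 2.53 ± 0.29. Of 20 macrophage markers 17 rose, 0 fell and 3 did not pass (20 rose adjusted over the list alone, camera adjusted p = 1.08e-07, adjusted p = 0.311 with an estimated correlation). Adgre1 stood at 1.93 ± 0.36. Among oxidative phosphorylation genes (25 measured) 0 rose, 24 fell and 1 did not pass (24 fell adjusted over the list alone, camera adjusted p = 2.95e-14, adjusted p = 0.291 with an estimated correlation). Sdha stood at -0.86 ± 0.11. Of 20 fatty acid oxidation genes 0 rose, 15 fell and 5 did not pass (17 fell adjusted over the list alone, camera adjusted p = 4.38e-08, adjusted p = 0.3 with an estimated correlation). Ppargc1a stood at -0.84 ± 0.18. Ttn was not called (-0.25 ± 0.13 as deposited), but array weights called it lower (-0.25) and quantile normalization higher (0.26, adjusted p = 0.0362). The Arrdc2 call (-1.87 ± 0.74) ended under 8 alternatives, with a largest adjusted p of 0.129.

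Against the wild-type response, the heterozygous response differed in 2626 genes, 1340 with a higher and 1286 with a lower response. Ankrd1 (6.51 ± 0.90, adjusted p = 1.03e-06), Cilp (5.21 ± 0.58), Csrp3 (4.63 ± 1.01, adjusted p = 0.000853), Ankrd2 (2.98 ± 0.83), Col1a1 (2.66 ± 0.50) and Trim63 (0.85 ± 0.24) responded more strongly in heterozygous muscle, and Ces1d (-2.42 ± 0.56) and Ppargc1a (-0.96 ± 0.27) less. Of 24 mechanosensing genes 12 were higher, 1 were lower and 11 did not pass (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000192, adjusted p = 0.348 with an estimated correlation). The Ankrd2 difference ended without wild-type saline replicate 1 (adjusted p = 0.06), and that of Cdkn1a (1.61 ± 0.42) stood at 0.13 between the AAV-injected muscles. Voom ended the differences of Krt18 (4.38 ± 0.66), Myh3 (4.28 ± 0.86) and Adgre1 (2.03 ± 0.53), with largest adjusted p of 0.238, 0.071 and 0.143.

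At 7 dpi the homozygous and heterozygous responses, at transgene levels 3.84-fold apart, differed in 422 genes, 331 lower and 91 higher in homozygous muscle. Among the lower responses were those of mechanosensing genes, with Csrp3 at -4.25 ± 0.94, adjusted p = 0.00403, Ankrd2 at -3.48 ± 0.78, adjusted p = 0.00428, Fhl1 at -2.27 ± 0.45 and Xirp2 at -1.68 ± 0.21, and of Uchl1 (-2.37 ± 0.48) and Mustn1 (-2.34 ± 0.51). Of 24 mechanosensing genes 0 were higher, 8 were lower and 16 did not pass (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 1.62e-10, adjusted p = 0.11 with an estimated correlation). Of 22 chaperone genes 0 were higher, 5 were lower and 17 did not pass (11 lower adjusted over the list alone, camera adjusted p = 3.02e-10, adjusted p = 0.11 with an estimated correlation). Hspb1 stood at -2.64 ± 0.34. Of 26 sarcomere genes 0 were higher, 6 were lower and 20 did not pass (10 lower adjusted over the list alone, camera adjusted p = 1.39e-07, adjusted p = 0.42 with an estimated correlation). Klhl41 stood at -1.14 ± 0.17. Homozygous muscle had the higher response in Mmp13 (3.60 ± 0.62), Serpina3n (2.73 ± 0.35), Tnfaip2 (2.00 ± 0.33) and Ccn5 (1.73 ± 0.33). In homozygous muscle Csrp3 stood at 424 ± 383 normalised counts after saline (SD, n = 4) and 276 ± 86 after AAV (n = 5), and in heterozygous muscle at 90.6 ± 77.8 and 1136 ± 255 (n = 4 and 4). Ankrd1, at -2.23 ± 0.84, adjusted p = 0.16, was not called, passed under 2 alternatives and stood at 0.27 between the AAV-injected muscles. Between those muscles 1399 genes were called and the differences of Myl2 (-3.62 ± 0.90) and Uchl1 ended, the count was 278 without homozygous saline replicate 1, and count-based tests ended the Mmp13 and Serpina3n differences (largest adjusted p = 0.67 and 0.202).

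Saline-injected homozygous muscle differed from saline-injected wild-type muscle. Cilp was higher by 3.31 ± 0.43 at 3 dpi, 4.97 ± 0.43 at 7 dpi and 5.21 ± 0.40, adjusted p = 2.48e-13 at 21 dpi, where it stood at 526 ± 184 against 13.1 ± 4.46 normalised counts (SD, n = 4 and 4). Myom3, a myomesin of the M-band, was higher by 2.60 ± 0.42, 2.64 ± 0.42 and 3.49 ± 0.39. Csrp3 was higher by 2.86 ± 0.74 at 3 dpi and 4.14 ± 0.68, adjusted p = 5.76e-05 at 21 dpi, and Ankrd1 and Ankrd2 by 3.15 ± 0.61 and 3.07 ± 0.56 at 21 dpi. At 7 dpi Eda2r, a receptor induced by p53 (2.71 ± 0.26), was higher. Adamts8, a secreted protease, stood lower, at -2.78 ± 0.48, -2.54 ± 0.48 and -2.17 ± 0.45. Ttn stood at 0.36 ± 0.14, 0.34 ± 0.14 and 0.33 ± 0.13, none of them called except with array weights, the block or only these groups fitted.

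In these saline muscles 297 genes were called at 3 dpi (222 higher), 271 at 7 dpi (212 higher) and 432 at 21 dpi (338 higher), and 117 were higher and 7 lower on all 3 days. The libraries of the 3 days are separate, and 158 genes were higher at both 3 and 21 dpi, against 5.8 for independent lists. At 21 dpi, of 24 mechanosensing genes 10 were higher, 0 were lower and 14 did not pass (13 higher adjusted over the list alone, camera adjusted p = 1.78e-10, adjusted p = 0.0841 with an estimated correlation). Fhl1 stood at 1.76 ± 0.32. Of 22 chaperone genes 9 were higher, 0 were lower and 13 did not pass (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.03e-08, adjusted p = 0.224 with an estimated correlation). Hspb7 stood at 2.33 ± 0.37. Of 26 sarcomere genes 8 were higher, 0 were lower and 18 did not pass (11 higher adjusted over the list alone, camera adjusted p = 4.35e-10, adjusted p = 0.249 with an estimated correlation). The counts fell to 68 without wild-type saline replicate 2, 140 without replicate 3 and 100 without homozygous saline replicate 3 at 3 dpi, to 155 and 150 without wild-type replicates 2 and 3 and 162 and 157 without homozygous replicates 1 and 3 at 7 dpi, and to 285 without wild-type replicate 2 and 275 without homozygous replicate 1 at 21 dpi. The calls of Csrp3, Sln (3.08 ± 0.49) and Myl2 (2.63 ± 0.71) at 3 dpi and Arrdc2 (-2.49 ± 0.74) at 21 dpi ended under 6, 1, 8 and 12 alternatives, and voom ended those of Adamts8 at 7 and 21 dpi (largest adjusted p = 0.109 and 0.0955).

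**Figure D3:**
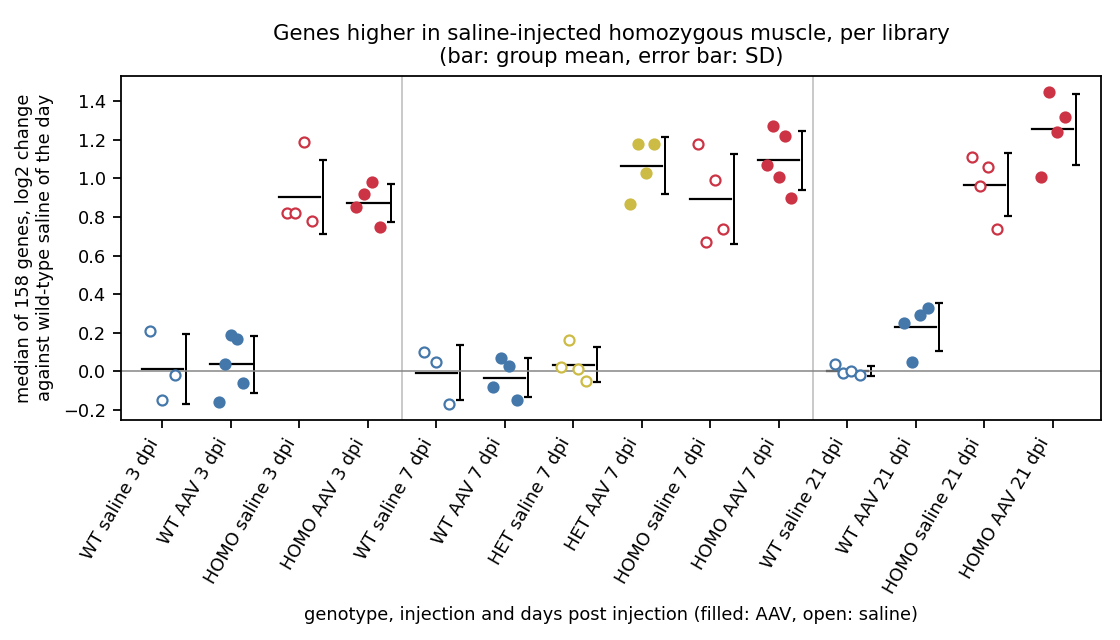
Median log2 level, against the saline-injected wild-type muscles of the same day, of the 158 genes called higher in saline-injected homozygous muscle at 3 and 21 dpi (vertical axis), per library (points) and as group mean and SD (bars). Over the group means the medians of homozygous saline muscle are 0.86 to 0.99, where the 3 and 21 dpi values follow from how the genes were chosen, while those of heterozygous muscle are 0.03 after saline and 1.03 after AAV.

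Saline-injected heterozygous muscle differed from wild-type muscle in 26 genes at 7 dpi, 17 higher and 9 lower, among them genes of the circadian clock. Of 15 clock genes 3 were higher, 2 were lower and 10 did not pass (8 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000102, adjusted p = 0.184 with an estimated correlation). The core clock gene Arntl stood at -1.89 ± 0.30, adjusted p = 0.000876, Per2 at 1.89 ± 0.39, adjusted p = 0.03, and Per3 at 1.24 ± 0.29. Pdk4, a kinase that restrains pyruvate oxidation (chromosome 6, 5483351 to 5496309), stood at 180 ± 52.5 against 1091 ± 386 normalised counts (SD, n = 4 and 3, -2.59 ± 0.59, adjusted p = 0.0469), and Cdkn1a stood at -1.48 ± 0.31. The count was 0, 0 and 71 without wild-type replicates 1, 2 and 3, and 5, 4, 7 and 5 without heterozygous replicates 1 to 4. The calls of Per2, Per3, Pdk4, Cdkn1a and Arntl ended under 10, 14, 11, 8 and 3 alternatives.

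Between 3 and 7 dpi the homozygous response changed in 776 genes, 365 with a higher and 411 with a lower response at 7 dpi (510 genes when only the groups compared were fitted and 1433 with array weights). Myh8 (4.97 ± 0.73, adjusted p = 1.8e-05), Myh3 (4.70 ± 0.81, adjusted p = 0.000163) and the growth factor gene Igf2 (2.97 ± 0.51) gained, and Nmrk2 (-2.41 ± 0.43) and Trim63 (-0.89 ± 0.23) lost. Of 8 developmental contractile genes 5 were higher, 0 were lower and 3 did not pass (6 higher adjusted over the list alone, camera adjusted p = 2.79e-07, adjusted p = 0.0935 with an estimated correlation). Of 19 stress and unfolded protein response genes 0 were higher, 12 were lower and 7 did not pass (14 lower adjusted over the list alone, camera adjusted p = 1.94e-17, adjusted p = 2.25e-06 with an estimated correlation). The transcription factor gene Atf4 stood at -1.31 ± 0.16 and the chaperone gene Hspa5 at -1.37 ± 0.16. Of 18 ribosome biogenesis genes 0 were higher, 6 were lower and 12 did not pass (13 lower adjusted over the list alone, camera adjusted p = 4.34e-09, adjusted p = 0.0017 with an estimated correlation). Count-based tests ended the gain of Mmp13 (3.35 ± 0.62), and voom the losses of Spp1 (-2.62 ± 0.66), Ccl2 (-2.20 ± 0.38) and Psat1 (-1.88 ± 0.45), with largest adjusted p of 0.788, 0.191, 0.354 and 0.111.

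Between 7 and 21 dpi 1798 genes changed in response, 982 higher and 816 lower (615 genes when only the groups compared were fitted and 3063 with array weights). Iigp1 (4.28 ± 0.86), Gbp6 (4.10 ± 0.75) and Cxcl9 (4.06 ± 0.64, adjusted p = 2.01e-05) gained, while Postn (-2.25 ± 0.52) and the chaperone gene Clu (-1.49 ± 0.31) lost. Of 13 T and natural killer cell markers 13 were higher, 0 were lower and 0 did not pass (13 higher adjusted over the list alone, camera adjusted p = 7.6e-24, adjusted p = 0.0352 with an estimated correlation). Lck stood at 2.77 ± 0.36. Of 4 B and plasma cell markers 4 were higher, 0 were lower and 0 did not pass (4 higher adjusted over the list alone, camera adjusted p = 3.48e-06, adjusted p = 0.0352 with an estimated correlation). Igkc stood at 5.19 ± 0.57. Of 16 antigen presentation genes 16 were higher, 0 were lower and 0 did not pass (16 higher adjusted over the list alone, camera adjusted p = 4.15e-20, adjusted p = 0.06 with an estimated correlation). The Cd8a gain (3.07 ± 0.46, adjusted p = 9.78e-06) stood at -0.29 with edgeR on the recovered reads, the Adgre1 gain (1.52 ± 0.49) ended under 9 alternatives and the Cthrc1 loss (-1.82 ± 0.44) under 3, and voom ended the gains of Igkc and Lck (largest adjusted p = 0.103 and 0.0947). The count was 1061 without homozygous AAV replicate 1 at 21 dpi and 3245 without replicate 4.

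**Figure D4:**
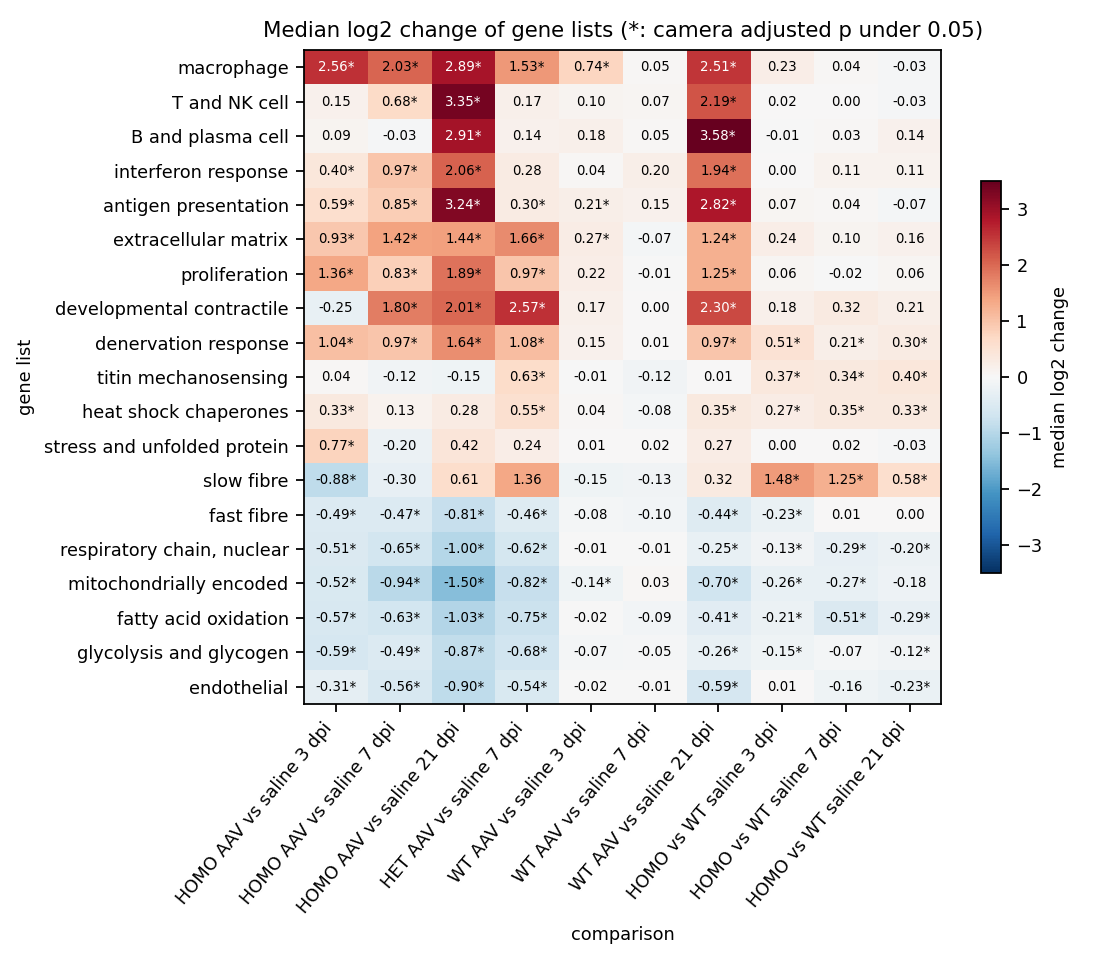
Median log2 change of gene lists (rows) in the AAV against saline comparisons and in homozygous against wild-type saline muscle (columns), as deposited, on a colour scale in log2 units. Immune lists rise most at 21 dpi and energy lists fall in homozygous and heterozygous muscle.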

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

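Tests of chromosome 2 and of dissection time or batch were chosen before. The other tests of causes here were chosen only after the result was seen.

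Saline-injected homozygous muscle held 158 genes above the wild-type level at both 3 and 21 dpi. Strain DNA linked to titin is argued against by the 8.2% of the set on chromosome 2 (13 of 158, against 7.9% of tested genes, Fisher exact one-sided p = 0.48), and virus by the 9 of 12 homozygous saline libraries that held 0 transgene reads, with at most 6 in the others. RNA from macrophages, fibroblasts or satellite cells, endothelial cells, pericytes or Schwann cells is argued against, as the whole cause, by the medians of their marker lists, which lay between -0.33 and 0.26 at 3, 7 and 21 dpi (SD of the members at most 0.29, 2 of 15 called higher), below the 0.7 to 1.05 that the fold of the set would give them. RNA from T cells cannot be told apart, because their markers lie so low that the same fold would move their median, at most 0.02, by only 0.1 to 0.16 (SD at least 0.1). Values at 7 dpi that were high by chance are argued against by a median homozygous minus heterozygous response of -0.93 in genes chosen on the other days. In heterozygous muscle the virus raised this set by a median of 1.05 (130 of 158 genes rose). Of 10000 random sets matched on mean value the highest gave 0.13, but these cannot test cleavage, as the set was chosen for its changes. In wild-type muscle, where TEV has no site in titin, 0 of them rose at 7 dpi (median -0.03), but 54 rose and 13 fell at 21 dpi (median 0.22), so part of the set also changed without cleavage. One hypothesis is that these genes respond to cleaved titin and are already raised in homozygous muscle before injection, and a difference in housing, litter or batch between the genotypes stays open, as untested.

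Transgene messenger RNA in homozygous muscle at 7 dpi lay 10.6-fold below the wild-type level. Dilution of muscle RNA by RNA from other cells is argued against, as the whole cause, by a median change of -0.47 in the fast fibre list, which stood at 0.03 under quantile normalization. The shallow library of the homozygous group is argued against by a log2 difference of -3.51 without it. Less virus delivered to these muscles cannot be told apart from other causes of the log2 difference of -3.41, because these data hold no measure of vector DNA. At 21 dpi the difference was -0.17.

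Clock genes differed between saline-injected heterozygous and wild-type muscle at 7 dpi. The same difference in AAV libraries correlated with it at 0.75 across the 15 clock genes (12 with the same sign). Another dissection time or batch for the heterozygous animals would give this. An allele effect shared with homozygous muscle is argued against by correlations of -0.72 and -0.13 with its saline difference at 3 and 21 dpi. Median absolute differences from wild-type muscle were 0.83 in heterozygous and 0.21 and 0.28 in homozygous muscle at 3 and 21 dpi. Time and batch, which no label gives, another difference of these animals and an effect in heterozygotes alone stay open.

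In 10 of the 175 groups of libraries tested, 1 library lay far from the rest by the Dixon test, and chance flags about 1 in 20 groups, or 8.8 of these. Ankrd1 stood at 13.3 normalised counts in wild-type AAV replicate 3 at 7 dpi (others 3.67 to 5.27), and Ankrd2 at 95.1 in wild-type AAV replicate 1 at 21 dpi (others 16.1 to 29). In wild-type AAV replicate 3 at 3 dpi Myh3 stood at 73.9 (others 1.7 to 17.7), Adgre1 at 10.6 (others 4.46 to 5.69) and Cd8a at 0.197 (others 0.0251 to 0.074). Myh3 stood at 15.9 in homozygous saline replicate 3 at 21 dpi (others 7 to 7.89), Cd8a at 0.436 in replicate 2 of that group (others 0.0654 to 0.104), and Trim63 at 178 in homozygous saline replicate 3 at 3 dpi (others 157). Homozygous AAV replicate 2 at 7 dpi held 6.9 M reads (others 19.7 M to 24.3 M), and homozygous saline replicate 1 at 21 dpi 19.8 M (others 26.2 M to 27.1 M).

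Responses of the genes named in every comparison differed between groups in 25 of 91 tests of the difference itself. Homozygous minus wild-type responses differed at 3 dpi in Ankrd1 (2.93), Trim63 (1.03) and Ppargc1a (-0.81), and at 21 dpi in Cd8a (1.7). At 7 dpi they differed in Ankrd1 (4.28), Myh3 (3.21), Col1a1 (2.6), Adgre1 (2.32), Ppargc1a (-0.97) and Ttn (-0.52, but 0.15 under quantile normalization). Heterozygous minus wild-type responses differed in Ankrd1 (6.51), Csrp3 (4.63), Myh3 (4.28), Ankrd2 (2.98), Col1a1 (2.66), Adgre1 (2.03), Cdkn1a (1.61), Trim63 (0.85) and Ppargc1a (-0.96). Homozygous minus heterozygous responses differed in Csrp3 (-4.25) and Ankrd2 (-3.48). Within homozygous muscle the response changed from 3 to 7 dpi in Myh3 (4.7) and Trim63 (-0.89), and from 7 to 21 dpi in Cd8a (3.07) and Adgre1 (1.52).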

How the results depend on the processing

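The voom fit, the direct comparison of homozygous with heterozygous AAV muscle, the rescaled transgene values and the reading of list directions under other scalings were tests chosen only after the result was seen, and the other alternatives were planned. For 24 main results, 420 of 493 alternative values kept their direction and side of the threshold, or for counts stayed within 1.5 times. The rest were 61 counts that moved further, 9 differences of the transgene whose unadjusted p no longer passed, and 3 that changed sign. For the 314 gene results, 6954 of 7334 values kept direction and side, 363 no longer passed, 9 newly passed and 8 changed sign, and 233 genes and comparisons kept all theirs. The counts for AAV against saline in homozygous muscle (3391 to 5075, 4883 to 5535 and 6799 to 8061 without single libraries at 3, 7 and 21 dpi), in heterozygous muscle (4318 to 5172) and in wild-type muscle at 21 dpi (3973 to 5819) stayed within 1.5 times under every alternative run. Without the shallowest library, homozygous AAV replicate 2 at 7 dpi, the homozygous count was 5051 and its difference from the wild-type response 2154.

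Array weights gave 1 gene in wild-type muscle at 3 dpi, 2944 and 2269 genes for homozygous minus wild-type at 3 and 21 dpi, 4075 for heterozygous minus wild-type, 895 for homozygous minus heterozygous, 834, 757 and 1119 for homozygous against wild-type saline at 3, 7 and 21 dpi, 205 for heterozygous saline, and 1433 and 3063 for the changes from 3 to 7 and from 7 to 21 dpi. Direct comparison of AAV muscles gave 5326, 6752 and 3573 genes for homozygous against wild-type at 3, 7 and 21 dpi, 5230 for heterozygous against wild-type and 1399 for homozygous against heterozygous, and differs by construction because it holds the difference between saline muscles. Fitting only the groups compared gave 121 for homozygous minus wild-type at 21 dpi, 1013 for homozygous saline at 21 dpi, 41 for heterozygous saline, and 510 and 615 for the changes over time. DESeq2 gave 8 and 7 genes in wild-type muscle at 3 and 7 dpi. In heterozygous saline muscle, no filter gave 17 genes, quantile normalization 12, robust variance estimation 13, edgeR 13, DESeq2 62 and voom 12. Of 253 calls of gene lists, 9 held with an estimated correlation and 168 with fry, which made 208 calls. For these counts the cause was not tested.

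With the replicate number as a block the count was 801 for homozygous minus wild-type at 3 dpi, and 587, 668 and 788 for homozygous against wild-type saline at 3, 7 and 21 dpi, while the other blocked counts stayed within 1.5 times. Outside the 2 sets named in the processing, correlations of same-numbered libraries ran from -0.24 to 0.31 and in none did every sample correlate best with its own number (2 of 4 in homozygous muscle at 3 dpi, 0 of 4 at 7 dpi, 2 of 4 in wild-type muscle at 21 dpi, and 1 and 2 of 3 at 3 and 7 dpi).

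Without single libraries the counts ran from 625 to 2314 (homozygous minus wild-type, 3 dpi), 404 to 1992 (21 dpi), 278 to 433 (homozygous minus heterozygous), 68 to 313, 150 to 263 and 275 to 405 (homozygous saline at 3, 7 and 21 dpi), 0 to 71 (heterozygous saline) and 1061 to 3245 (7 to 21 dpi). The transgene difference of homozygous from wild-type muscle ran from 1.55 to 2.52 at 3 dpi, where 8 of 9 values no longer passed an unadjusted exact permutation test, and from -0.94 to 0.47 at 21 dpi. That of heterozygous from wild-type muscle ran from -1.65 to -1.28. Direction changed for Ttn under quantile normalization (0 in homozygous muscle at 3 dpi, 0.21 at 7 dpi, 0.43 at 21 dpi, 0.26 in heterozygous muscle and 0.15 for homozygous minus wild-type at 7 dpi). It changed between AAV muscles for Ankrd1 in homozygous against heterozygous (0.27) and Myl2 in homozygous against wild-type muscle (0.15), and with edgeR for Cd8a from 7 to 21 dpi (-0.29). For these the cause was not tested. DESeq2 gave no adjusted p for 1 gene in most comparisons, 254 for 2 of them and 758 for the change from 3 to 7 dpi.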

Other observations

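Most of 15 genes that muscle raises when its nerve is lost rose after the virus in homozygous and wild-type muscle at 21 dpi and in heterozygous muscle, but these calls of the list did not hold with an estimated correlation. Of the 15 genes 12 rose, 2 fell and 1 did not pass (12 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000307, adjusted p = 0.24 with an estimated correlation) in homozygous muscle at 21 dpi, beside a median macrophage rise of 2.89, and 10 rose, 2 fell and 3 did not pass (10 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000815, adjusted p = 0.196 with an estimated correlation) in wild-type muscle at 21 dpi. The transcription factor gene Runx1 stood at 2.69 ± 0.31, 2.17 ± 0.30 and 3.22 ± 0.31 at 3, 7 and 21 dpi in homozygous muscle, 2.54 ± 0.31 in heterozygous muscle and 2.36 ± 0.31 in wild-type muscle at 21 dpi. The adhesion molecule gene Ncam1 rose by 3.05 ± 0.31 in heterozygous muscle and by 2.75 ± 0.31 in homozygous muscle at 21 dpi, where Myog, a transcription factor of muscle differentiation, rose by 3.35 ± 0.42. In heterozygous muscle, denervation genes (15 measured) 11 rose, 2 fell and 2 did not pass (12 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.36e-05, adjusted p = 0.281 with an estimated correlation). Rgs5, a marker of pericytes, fell in each of these comparisons, at -0.67 ± 0.15, -0.81 ± 0.15, -1.45 ± 0.15, -0.64 ± 0.15 and -1.08 ± 0.15. Of 11 Schwann cell genes 0 rose, 6 fell and 5 did not pass (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0306, adjusted p = 0.473 with an estimated correlation) in wild-type muscle at 21 dpi. The myelin gene Prx stood at -1.09 ± 0.27.

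Some slow fibre genes and some targets of p53 were higher in saline-injected homozygous muscle. Of 12 slow fibre genes 2 were higher, 0 were lower and 10 did not pass (8 higher adjusted over the list alone, camera adjusted p = 3.61e-07, adjusted p = 0.179 with an estimated correlation) at 7 dpi. Myoz2, which encodes a calcineurin-binding protein of the Z-disc, stood at 1.84 ± 0.35 at 21 dpi, and Myl2 at 2.89 ± 0.71 at 7 dpi, a call that ended under 7 alternatives (largest adjusted p = 0.276). In heterozygous muscle the virus raised Casq2, the slow and cardiac calsequestrin, by 1.55 ± 0.23, and the slow troponin gene Tnnt1 by 2.62 ± 0.54. Of 16 p53 target genes 2 were higher, 0 were lower and 14 did not pass (3 higher adjusted over the list alone, camera adjusted p = 0.000631, adjusted p = 0.0841 with an estimated correlation) in homozygous saline muscle at 21 dpi. Eda2r stood at 2.37 ± 0.26, 2.71 ± 0.26 and 2.59 ± 0.24 at 3, 7 and 21 dpi in saline muscle, and at 3.41 ± 0.24 in heterozygous muscle after AAV, where Bbc3, which promotes apoptosis, rose by 1.45 ± 0.23.

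Regrouping the same samples, a test chosen before the result was seen, called chance excluded at an unadjusted share of splits under 0.05. Chance can be excluded for AAV against saline in homozygous muscle at 3 dpi (1 of 35 splits as large, the real one, with 4505 genes and at most 2443 in the others) and 7 dpi (1 of 100, 5616 and 4608) and in wild-type muscle at 21 dpi (1 of 35, 5329 and 2937). In homozygous muscle at 21 dpi (1 of 35, 7714 and 5882) and heterozygous muscle (1 of 35, 5259 and 929) same-numbered samples counted as pairs by the limit on correlations. The 7 other splits that part all pairs, with at most 5113 and 466 genes, are too few for a share under 0.05. In wild-type muscle at 3 and 7 dpi (0 genes) the splits decide nothing, as each of the 56 and 35 gives at least 0 (at most 13 and 29).

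For differences between responses chance can be excluded for homozygous minus wild-type at 7 dpi (2 of 100 splits as large, 2623 genes and at most 2998 in the others) and the change from 3 to 7 dpi (2 of 100, 776 and 855), and cannot for homozygous minus wild-type at 3 dpi (5 of 100, 1269 and 2216). Splits that ignore the pairs of a paired set decide nothing for heterozygous minus wild-type (4 of 100, 2626 and 3165), homozygous minus heterozygous (1 of 100, 422 and 68) and the change from 7 to 21 dpi (2 of 100, 1798 and 2111). Chance cannot be excluded either for homozygous minus wild-type at 21 dpi (14 of 100, 732 and 2926). The split with 2926 genes points to a structure of these samples whose cause was not tested. Chance can be excluded for homozygous against wild-type saline muscle at 3 (297 and 98), 7 (271 and 119) and 21 dpi (432 and 1). Each share was 1 of 35, the lowest possible, as for heterozygous against wild-type (26 and 0). That count was 0 without wild-type replicate 1 or 2, so chance stays open.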
